A study of Macaca mulatta with 4 samples.

How the data were processed

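H3K27me3 was profiled by the submitters in rhesus macaque morulae, with 2 libraries labelled AG and 2 labelled GG. The assay is CUT&RUN per the labels' extraction protocol and the series title, although the sample titles name ChIP-seq. Groups and replicate numbers were taken from the sample labels, and no label pairs a replicate of AG with a replicate of GG. Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, SAMtools, SICER 1.1 and deepTools 3.3.1, with the build rheMac8; versions of the first 3 are not given in the sources used here. SICER joins enriched windows separated by no more than a gap into islands, which suits broad marks. The names of the deposited files give a SICER window of 200 bp, a gap of 200 bp and an E value of 0.001 for AG, and a window of 300 bp, a gap of 1200 bp and the same E value for GG, with tags filtered to islands, called for each library separately.

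The deposited files hold a chromosome, a start and an end per line and no count, score or strand. Examined here, the intervals of a file were sorted and neither overlapped nor touched, with lengths from 20 bp upwards and a most common length of 150 bp. They were read as stretches of bases covered by tags on islands with overlapping tags joined; how tags were joined is not stated. Coverage as deposited therefore records where islands with tags lie and how many bases are under tags, and neither tag number nor sequencing depth can be recovered. A larger gap keeps more tags between windows, and a deeper library passes the E value in more windows, so both raise the covered bases. No control library was used here.

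The tests had been planned before the data were examined on the assumption of a line per tag. Since intervals are joined tags, a tag was replaced by 150 bp of covered bases. A bin of 10 kb was marked with at least 450 covered bases (3 tag lengths), and a group's marked bins were those marked in both of its libraries. Chromosome span was the highest interval end over all libraries, which sums to 2834 Mb. Overlap of marked bins was compared with 1000 circular shifts within chromosomes under a fixed seed (one-sided). Domains joined intervals at most 1500 bp apart and kept at least 450 covered bases. Values were set side by side as mean ± SD over 2 libraries.

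Bins with at least 750 covered bases in 2 or more libraries were tested with limma 3.58.1 (lmFit, then eBayes with trend) on log2 covered bases scaled to each library's total, with a prior of 300 bases scaled likewise, coded as AG minus GG, with Benjamini-Hochberg adjustment at 0.05 and no block for replicate number. Scaling to totals had been planned for tags. Covered bases in a bin stop at 10000 and cannot rise in proportion to a total, so the scaled fit lowers bins that are full in GG, while a fit without scaling reads any difference in depth as a difference in coverage. Neither separates depth from the mark, and both are reported. Named bins followed the rule fixed for a build without annotation, which takes the 5 highest and 5 lowest log2 differences past the threshold, with ties ordered by position; the 5 widest domains covered in both libraries of a group were also named. The first 2 Mb of X and the correlations across chromosomes were chosen after the data were seen.

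The bin test was tested on simulated data made for AG against GG. With 200 changed of 29825 bins and equal totals, 42.4% of bins changed by 2 and 66% of bins changed by 4 on the log2 scale were called in the right direction, and 0.0338% of unchanged bins were called. With 12000 changed of 30065 bins these shares were 83.4%, 93.4% and 2.89%. With coverage in proportion to the observed library totals and a ceiling at the bin size, the scaled fit called 63.1% of unchanged bins (29815 bins) and the unscaled fit 98.3% (29850 bins). The permutation test of overlap gave 0.995 times the shifted overlap with no planted overlap (permutation p = 0.54) and 2.70 times with a planted one. These simulated bins were scattered uniformly, so regional preferences common to both sets were not tried.

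Replicates were checked for identity, and at most 68 intervals were identical between any 2 libraries. Alternatives covered the bases that mark a bin, the bin size, thinning to 42512 intervals, the scaling, the added bases, the filter, a replicate block, the joining distance and leaving out each library in turn. In the fits without a library, the bins of the full fit were kept, a choice made after seeing that refiltering dropped bins covered in 1 group, and the lone sample of a group is assumed to vary like the other group. Putting all libraries under a common clustering rule (intervals at most 200 bp apart joined, clusters of at least 1000 bp kept) was chosen after seeing the data. Promoters, gene lists and genomic features were planned and not run, since no annotation or sequence of rheMac8 was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.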

Results

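Trimethylation of lysine 27 on histone H3 (H3K27me3), the repressive mark laid down by the Polycomb repressive complex PRC2, was profiled by CUT&RUN in rhesus macaque (Macaca mulatta) morulae. In CUT&RUN an antibody guides a protein A-micrococcal nuclease fusion to the mark, and the DNA released by the nuclease is sequenced. There were 2 libraries from embryos labelled AG and 2 from embryos labelled GG, which the series describes as androgenetic embryos (nuclear genome from the father only) and gynogenetic embryos (nuclear genome from the mother only). The series concerns genomic imprinting before implantation, so the comparison asked where H3K27me3 lay on a paternal and on a maternal genome. Each library was represented by genomic intervals on rheMac8, which are stretches of bases under tags on islands called enriched by the submitters, with 42512 and 44337 intervals in AG replicates 1 and 2 and 362999 and 287230 in GG replicates 1 and 2. The intervals carry no tag counts, so sequencing depth is unknown. A base outside an interval was under no tag kept on a called island, which does not make it free of the mark. Islands were called with another window and gap in AG than in GG, so the calling settings and the groups fully coincide. Nothing in the labels says that replicates came from separate embryo pools, and p-values across libraries then measure only the spread between these samples, which may be technical.

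H3K27me3 intervals were scarce in AG and broad in GG. They covered 0.537% ± 0.0919 of the spanned genome in AG and 7.58% ± 0.400 in GG (SD, n = 2 each), or 15.2 ± 2.60 Mb against 214.9 ± 11.3 Mb, a ratio of 14.1. Every autosome had a higher covered percentage in both GG libraries than in both AG libraries. Of 283406 bins of 10 kb, 5527 and 8383 were marked in AG replicates 1 and 2 and 38706 and 31773 in GG replicates 1 and 2. Bins marked in both libraries numbered 3979 in AG (1.40%) and 29298 in GG (10.3%). The groups differed by more than the spread between replicates, but with 2 libraries against 2 the smallest p of an exact two-sided permutation test is 0.333, so no p is given. When every library was thinned at random to 42512 intervals, bins marked in both GG libraries numbered 7003 and the ratio of covered bases was 1.91, which with equal interval numbers only restates that GG intervals were longer; AG replicate 2 without replicate 1 had 8383 marked bins.

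**Figure D1:**
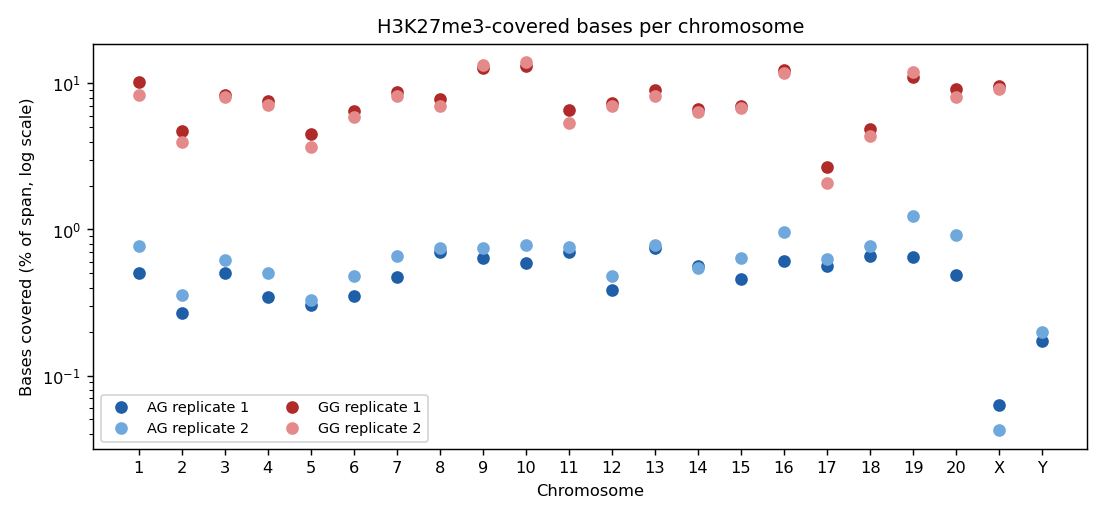
Covered bases as a percentage of each chromosome's span (y axis, log scale) for each of the 4 libraries (points), over chromosomes 1 to 20, X and Y. GG lay above AG on all autosomes, AG fell to 0.0625% and 0.0421% on X, and GG has no point on Y because no Y interval was listed.

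The overlap of marked bins was partial in every pair of libraries. The Jaccard index, the shared bins as a fraction of the bins marked in either library, was 0.401 between the AG libraries, 0.711 between the GG libraries and 0.0846 to 0.124 in the 4 pairs that crossed the groups. The sizes of the sets set much of this difference, since even full nesting of an AG library in a GG library would give at most 0.143 to 0.264. In bins, AG replicate 2 shared more with GG replicate 1 (4864) and GG replicate 2 (4436) than with AG replicate 1 (3979), while AG replicate 1 shared 3979 with AG replicate 2 and 3450 and 3209 with GG replicates 1 and 2. The index reached 60.8% of the highest its set sizes allow in the AG pair, 86.7% in the GG pair and 47.1% to 59.2% across the groups. In all 6 pairs the shared bins exceeded every one of 1000 circular shifts of one set along its chromosomes (one-sided permutation p = 0.001, the smallest these shifts can give). The lowest index within a group exceeded the highest between groups by 0.276, and by 0.587 without AG replicate 1 or 0.617 without AG replicate 2, which leave the GG pair alone as the within-group index. Thinned to 42512 intervals per library, the indices were 0.400 and 0.285 within AG and GG and at most 0.0833 across the groups, where full nesting would allow 0.341 to 0.538. The thinned GG pair itself reached only 30.0% of its highest possible index of 0.948. Random removal of GG intervals thus lowers any index with a GG library and leaves the AG pair nearly untouched. The thinned indices therefore do not show a separation of the groups at equal set size.

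**Figure D2:**
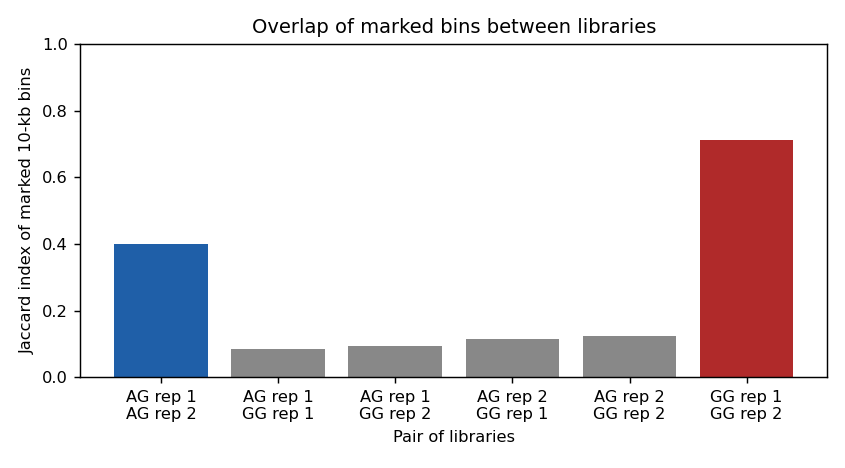
Jaccard index of marked 10-kb bins (y axis, no unit) for each of the 6 pairs of libraries (bars). The AG pair (blue, 0.401) and the GG pair (red, 0.711) stand above the 4 pairs that cross the groups (grey, at most 0.124), which the unequal set sizes limit to at most 0.264.

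Bins marked in AG included many also marked in GG and a smaller set with no GG coverage. Of the bins marked in both AG libraries, 2385 (59.9%) were also marked in both GG libraries, where they made up 8.14% of the GG bins. Independent placement gives 411 shared bins and circular shifts gave 432 on average and at most 590, so the overlap was 5.51 times the shifted one (one-sided permutation p = 0.001, the smallest possible). Both groups were denser toward autosome ends, and shifts move bins away from there. A preference for such regions in both groups may therefore exceed the shifts by itself. Per library, 52.9% to 62.4% of an AG library's bins were marked in a given GG library, and 20.5% to 25.9% after thinning to 42512 intervals, a fall that follows from removing mainly GG intervals. The shared bins held a median of 2345 and 2406 covered bases in AG replicates 1 and 2 and of 8050 and 8321 in GG replicates 1 and 2. Another 1229 bins, 30.9% of the AG bins, had no covered base in either GG library, with a median of 1975 and 1955 covered bases in the AG replicates. In the other direction, 23923 bins (81.7% of the GG bins) had no covered base in either AG library. Of all 283406 bins only 46797 had a covered base in any library, so lacking a base in the other group was the usual state of a bin. The AG bins without GG bases were spread over the genome, with 103 on chromosome 1, 100 on chromosome 3 and 99 on chromosome 8.

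H3K27me3 domains, made by joining intervals at most 1500 bp apart by the same rule in every library, were short in AG and long in GG. The intervals had already been filtered to islands called with a gap of 200 bp in AG and 1200 bp in GG. The wider gap can itself lengthen GG domains, so the widths are not on an equal footing. The N50, the width at which domains at least as wide hold 50% of the summed width, was 3765 ± 656 bp in AG and 26249 ± 5314 bp in GG (SD, n = 2 each). Domains of at least 100 kb numbered 0 in both AG libraries, 133 in GG replicate 1 and 237 in GG replicate 2. The widest GG domain covered in both libraries lay on chromosome 11 from 51161313 to 51485218 (323.9 kb, 92.3% and 96.5% covered in the GG replicates, 2.82% and 4.93% in the AG replicates). The next lay on chromosome 11 from 4936887 to 5223642 (286.8 kb), chromosome 8 from 42876662 to 43150573 (273.9 kb), chromosome 10 from 78485449 to 78730234 (244.8 kb) and chromosome 1 from 9942450 to 10178736 (236.3 kb), where AG coverage stayed between 2.82% and 11.2%. Thinned to 42512 intervals per library the N50 was 3731 bp in AG and 2790 bp in GG, but this thinning removes most GG intervals and few or no AG intervals, so it shortens GG domains by construction. Genes in these domains were not analysed here, since no annotation of rheMac8 was used.

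The widest AG domains differed in how far GG covered them. The widest, on chromosome 17 from 2334734 to 2388030 (53.3 kb), was covered to 92.3% and 92.1% in the AG replicates and to 59.2% and 77.2% in the GG replicates. Chromosome 13 from 103304327 to 103351458 (47.1 kb) was covered to 87.0% and 87.5% in AG and to only 8.02% and 29.9% in GG. On chromosome 11 from 36233371 to 36268592 (35.2 kb) the AG libraries were covered to 71.9% and 83.1%, whereas GG replicate 1 had 69.9% and GG replicate 2 had 0%. The remaining AG domains, on chromosome 12 from 63119798 to 63147633 (27.8 kb) and chromosome 9 from 96353549 to 96379831 (26.3 kb), were covered to at least 96.2% in both GG libraries.

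**Figure D3:**
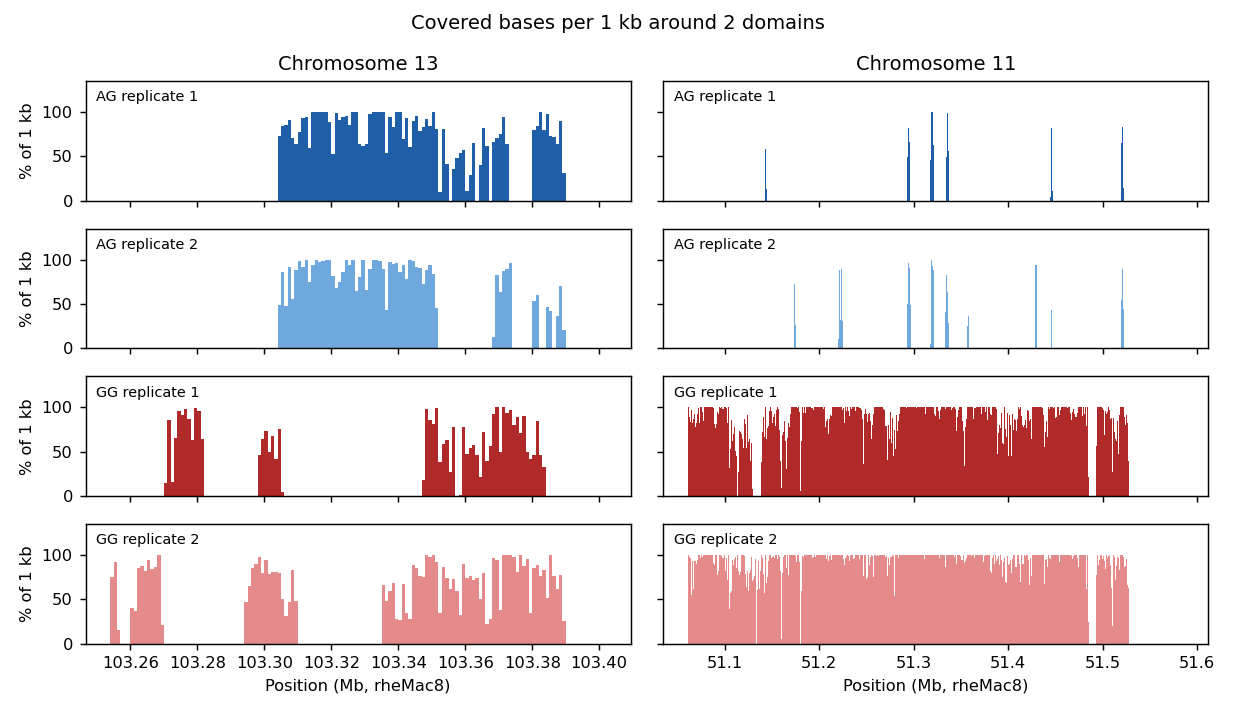
Covered percentage of each 1 kb (y axis) along rheMac8 position in Mb (x axis) for the 4 libraries (rows), around the AG domain on chromosome 13 (left) and the widest GG domain on chromosome 11 (right). The chromosome 13 domain is filled in both AG libraries (87.0% and 87.5%) and sparse in GG (8.02% and 29.9%), and the chromosome 11 domain is filled in both GG libraries (92.3% and 96.5%) and sparse in AG.

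Tested bin by bin as a share of each library's total, far more 10-kb bins had higher coverage in GG, and a smaller set had higher coverage in AG. Of 30536 bins tested with limma on log2 covered bases scaled to the library's total, 23090 were higher in GG and 3255 higher in AG at a Benjamini-Hochberg adjusted p under 0.05. Of the GG calls 23028 had no covered base in AG, and of the AG calls 1124 had none in GG. Such bins passed the filter through the covered group alone. Their calls therefore mostly restate that a bin was covered in only that group, and are no independent evidence of a difference. A higher share need not mean more covered bases. Of the AG calls 1896 lay in bins marked in all 4 libraries, and without scaling 30 of those bins were higher in AG and 1598 in GG. In simulated data with coverage following the library totals up to the ceiling, the scaled fit called 63.1% of unchanged bins and the unscaled fit 98.3%. If depth differed in that way, the adjusted p would not limit false calls. The bin with the largest AG excess was on chromosome 13 from 103310001 to 103320000, with 9137 and 9566 covered bases in AG and 0 in both GG libraries (limma log2 difference 7.90, SE 0.290, adjusted p = 0.000247). It was followed by chromosome 17 from 45680001 to 45690000, chromosome 13 from 103320001 to 103330000, chromosome 3 from 50840001 to 50850000 and chromosome 13 from 89160001 to 89170000, with log2 differences of 7.83, 7.75, 7.75 and 7.74. The GG extreme was a tie at the ceiling of 10000 covered bases in both GG libraries and 0 in both AG libraries (limma log2 difference −4.24, SE 0.0792, adjusted p = 7.55e-05), listed by position on chromosome 1 from 16930001 to 16940000 and from 220580001 to 220590000, chromosome 2 from 48520001 to 48530000 and from 55300001 to 55310000, and chromosome 4 from 70001 to 80000. On X, 1787 of 1866 tested bins were higher in GG and 20 higher in AG. Log2 differences of bins at 0 depend on the added prior of 300 bases and are no measured folds. Since the prior is scaled with the total, a bin at 0 in both libraries of a group has no spread there by construction. The SE and adjusted p of such calls rest on the other group and on variance shared across bins. For bins at the ceiling in both GG libraries, the GG spread comes only from the library totals.

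The direction in bins marked in all 4 libraries depended on the scaling, whereas a bin at 0 in both libraries of a group could hardly change direction. Under scaling to library totals, no scaling and median-of-ratios factors alike, 1176 bins were called higher in AG, 1123 of them without a GG base, and 23002 higher in GG, 22940 of them without an AG base. Of 2374 tested bins marked in all 4 libraries, 1896 were higher in AG and 0 in GG when scaled to totals, 30 in AG and 1598 in GG without scaling, and 527 in AG and 366 in GG with median-of-ratios factors. Over all tested bins, 12.4% of calls were higher in AG when scaled, and 4.33% without scaling (1176 in AG and 25989 in GG), with medians of −3.47 and −4.32 on the log2 scale. Median-of-ratios factors gave 1703 bins higher in AG, and leaving out a GG library gave 886 without replicate 1 and 859 without replicate 2. The GG count was 3359 after thinning, which removes mainly GG intervals, with 2618 bins higher in AG. It was 5 among bins covered in all 4 libraries, where 2190 were higher in AG. This last filter drops the GG calls without an AG base and leaves bins whose direction follows the scaling.

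The X chromosome was nearly bare of H3K27me3 intervals in AG and well covered in GG. X held 0.101 ± 0.0442 times the covered bases its length would give in AG and 1.23 ± 0.0165 times in GG (SD, n = 2 each). As a percentage of X, 0.0625% and 0.0421% were covered in AG replicates 1 and 2, against 0.497% and 0.635% of the autosomes, while GG replicates 1 and 2 covered 9.61% and 9.09% of X and 7.80% and 7.23% of the autosomes. What AG coverage X had was concentrated at its start: the first 2 Mb held 79.6% and 71.7% of the X bases in AG replicates 1 and 2, at 7.47 and 3.54 times the autosomal coverage. Without these 2 Mb, a region chosen after its coverage was seen, the AG ratio was 0.0238. The Y chromosome had 41 and 54 intervals in AG replicates 1 and 2, covering 19.4 and 22.2 kb (0.172% and 0.197%), and none was listed in either GG library. The difference on X exceeded the spread between replicates, and the smallest exact two-sided p with these numbers is 0.333.

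**Figure D4:**
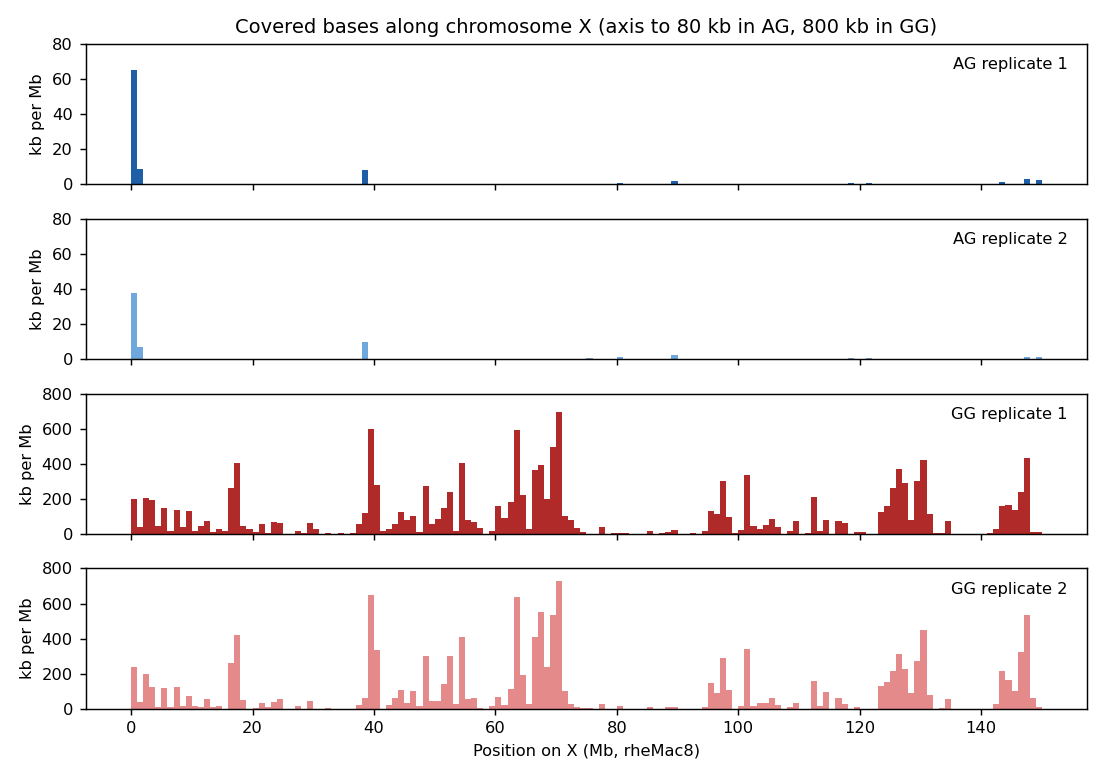
Covered bases in kb per Mb (y axis) along X in Mb (x axis) for the 4 libraries, with GG axes spanning 10 times the range of the AG axes. AG coverage stands mainly in the first 2 Mb (79.6% and 71.7% of the X bases), and GG coverage runs along the chromosome.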

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

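Chromosomes were compared by their covered percentage relative to that of the autosomes in the same library, and 3 of 21 were picked out because both AG libraries lay on one side of the autosomal level and both GG libraries on the other. These differences were not tested. If each library fell on either side independently and equally often, 12.5% of chromosomes would split so. The libraries are not independent in this sense, since AG and GG coverage rose together across autosomes, so that share is only a rough guide. The rule passes over some chromosomes with wider differences than chromosome 11. Chromosome 17 lay at 1.07 ± 0.104 times the autosomal level in AG and 0.316 ± 0.0381 times in GG (SD, n = 2 each). It was not picked because AG replicate 2 lay at 0.993 times. Chromosome 10 lay above that level in both groups, at 1.21 ± 0.0314 times in AG and 1.80 ± 0.178 times in GG. These were not tested either. The test on weaker X domains was set before its result was seen, and the other tests on X were chosen afterwards.

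Chromosome 11 lay at 1.30 ± 0.157 times the autosomal coverage in AG and 0.791 ± 0.0734 times in GG, a difference of 0.508 (SD, n = 2 each). Chromosome 18 lay at 1.28 ± 0.0762 times in AG and 0.612 ± 0.0128 times in GG, a difference of 0.665.

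X lay at 0.0961 ± 0.0422 times the autosomal coverage in AG and 1.24 ± 0.0178 times in GG, a difference of −1.15. Poor mapping on X is argued against by the GG libraries, whose X share over its share of length was at least 1.22. Poor calling on X under the AG settings is not, since GG was called with another window and gap. Among the 3979 most covered GG bins the X share over its share of bins was 1.08, so X was not underrepresented there. This cannot decide whether weaker X domains dropped out in AG. It would bear on this only if AG calls followed the GG ranking, which was not tested. Of the bins marked in both AG libraries, 30.9% had no GG base and so no place in that ranking. Fewer copies of X in the AG embryos and less H3K27me3 on X of paternal origin stay open. Both lower the AG share of X (0.101 of its share of length), and no input library was used here to give the copy number. Y intervals numbered 41 and 54 in AG replicates 1 and 2 and 0 in both GG libraries. They point to a Y chromosome in part of the AG material, which would lower its X copies. They do not give the number of X copies, so what each adds cannot be told apart. The first 2 Mb of X, where a pseudoautosomal region shared with Y might lie, had 5.51 ± 2.78 times the autosomal coverage in AG against 0.0225 times on the rest of X, but the region was picked for its coverage and autosome ends were also covered more than the rest, so this decides nothing.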

How the results depend on the processing

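The common clustering rule and the setting without the first 2 Mb of X were chosen after seeing the data. Some of the values counted next could not move. Leaving out an AG library cannot change the bins marked in GG, nor a GG library those marked in AG. The limits also differed between measures, so the tally is no measure of robustness by itself. Of the comparisons' values, 70 under alternatives stayed within their limits and 24 moved; the overlap of AG and GG bins stayed between 3.46 and 6.54 times the shifted one, with a permutation p of 0.001 throughout. The 10 named bins stayed past the threshold in 125 values under alternatives, which shows little, since they were picked as extremes with 0 bases in one group; none was tested among bins covered in all 4 libraries, nor the 5 GG bins after thinning. Bins marked in AG (3979) fell to 2411 at 10 tag lengths, and ranged from 3979 to 8383 with a library left out. Bins marked in GG (29298) were 49648 at 5 kb, 10505 at 50 kb and 7003 after thinning; bin size changes the number of bins by construction. The gap in Jaccard index (0.276) was 0.359 at 10 tag lengths, 0.302 at 5 kb, 0.201 at 50 kb, 0.201 after thinning and 0.276 to 0.617 with a library left out. Bins higher in AG (3255) were 1176 without scaling, 1703 with median-of-ratios factors and 859 to 4401 with a library left out (886 without GG replicate 1, 859 without GG replicate 2). Bins higher in GG (23090) were, with fewer bins tested, 5 among bins covered in all 4 libraries (2190 higher in AG) and 3359 after thinning (2618 higher in AG). The first of these leaves out bins at 0 in AG, which make up nearly all GG calls. The X ratio was 1.26 in GG from marked bins and 0.0238 in AG without the first 2 Mb of X. The N50 in GG was 17057 bp with intervals joined at 500 bp, 44865 bp at 5000 bp and 2790 bp after thinning, below the 3731 bp of AG; in AG it was 5409 bp at 5000 bp and 4440 bp for domains of at least 10 tag lengths. Where no construction is named, the cause was not tested. A replicate block gave 2908 bins higher in AG and 23032 in GG. Deviations of same-numbered libraries correlated at −0.0646 across bins. Bins at 0 in both libraries of a group deviate by 0 there, which pulls this value toward 0, so it cannot decide on pairing. The libraries share only a number, and no label pairs them. Depth is unknown, and thinning removes intervals rather than tags, mostly from GG, which lowers GG values by construction, so the effect of depth itself could not be measured. Voom weights and 1 tag per position and strand were not run, as both need tags; alternatives for promoters, gene lists and genomic features were not run.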

Other observations

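The tests in this part were all chosen after the results they bear on had been seen.

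H3K27me3 coverage rose toward the ends of autosomes in both groups. The outer 5 Mb at each end were covered 4.53 and 4.37 times as densely as the rest in AG replicates 1 and 2 and 2.86 and 3.44 times in GG replicates 1 and 2. Among windows of 1 Mb, AG coverage was highest on chromosome 11 between 36 and 37 Mb (220.9 and 236.6 kb in the AG replicates, 173.7 and 52.6 kb in the GG replicates) and on chromosome 8 between 13 and 14 Mb (197.2 and 185.4 kb in AG, 95.4 and 86.0 kb in GG). Of the 5 windows with the highest AG coverage, which were picked for that coverage, 4 had more covered bases in both AG libraries than in either GG library, chromosome 13 between 88 and 89 Mb among them (171.5 and 169.7 kb against 96.5 and 14.3 kb). The fifth, the first Mb of chromosome 8, did not (105.9 and 121.2 kb in AG, 121.9 and 129.3 kb in GG). The highest GG windows lay on chromosome 9 between 1 and 2 Mb (784.2 and 879.2 kb, with 54.0 and 46.8 kb in AG) and chromosome 6 between 2 and 3 Mb (777.8 and 877.5 kb).

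Across the 20 autosomes, which are not replicates, covered percentages of AG and GG rose together (Pearson r = 0.561, permutation p = 0.0102, adjusted p = 0.0204). Spearman rho was 0.537 (permutation p = 0.0174, adjusted p = 0.0261), and Pearson r was 0.443 without chromosomes 19 and 2. AG coverage was higher on shorter autosomes (r = −0.696, permutation p = 0.00065, adjusted p = 0.0039; rho = −0.644, permutation p = 0.0028, adjusted p = 0.0084; r = −0.757 without chromosomes 1 and 2). GG coverage showed no such relation past the threshold (r = −0.280, permutation p = 0.230; rho = −0.275, permutation p = 0.238; both adjusted to 0.238; r = −0.298 without chromosomes 1 and 2). Adjustment was over these 3 relations with 2 coefficients each.

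GG libraries covered 14.1 times as many bases as AG libraries. The wider gap and window in the GG calls stay open: a common clustering rule gave a ratio of 16.0, but it cannot restore tags that the AG calls removed, and it kept 83.3% of the covered bases in AG against 94.4% in GG. Deeper sampling of a landscape common to both groups is not decided by the 30.9% of AG bins without any GG base. GG was called with another window and gap, which may drop such bins. They may also be regions that gather tags in any library, and no control library was used here. Deeper sequencing of GG may account for some or all of the ratio. It cannot be told apart from a denser mark or from the wider gap and window in the GG calls. Bins marked in all 4 libraries held 2.48 times as many covered bases in GG, and each of these can give that. The parental origin of the genome stays open and untested.

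A set of bins was marked in both AG libraries and in no GG library. Scattered background in the AG libraries is argued against, because outside all bins marked in a GG library the AG libraries shared 1251 bins, 44.2 times the shifted overlap (permutation p = 0.001, the smallest possible). Regions that gather tags in any library prepared from little material may also recur between the AG libraries, which no control library was used here to test. A mark specific to the paternal genome is the hypothesis the design names, and it stays open and untested.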
